A study of Drosophila melanogaster with 3 samples.

How the data were processed

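Expression was measured on 3 two-colour spotted microarrays, each comparing RNA of flies kept in 13% CO2 for 24 h (Cy5) with RNA of flies kept in air for 24 h (Cy3). Per the labels' protocols, RNA was extracted with Trizol and each dye was incorporated as labelled dUTP during reverse transcription. The dyes had the same orientation on all 3 arrays, so a dye effect of a probe and its response to CO2 enter the ratio together. The 3 arrays form 1 group of replicates. The series' design text describes triplicate experiments, and where arrays did not come from separate sets of flies the p-values measure only the spread between these arrays.

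The values were the authors' deposited log2 ratios, 1 column per array. The background correction, normalization, spot filter, scanner and software are not given in the sources used here. The log base was checked on the values. Raising 2 to each deposited value gave a whole multiple of 0.001 for 100% of the values on each array (tolerance 5.1e-05 on the log scale), against 10.8% to 12.0% for the natural logarithm and 20.8% to 29.4% for base 10. The deposited values are therefore base-2 logarithms of linear ratios that had been rounded to 3 decimals. The lowest ratio on any array was 0.012, so rounding limits the precision of the most reduced probes. The medians of the deposited columns were -0.06, -0.00 and 0.09 for arrays 1, 2 and 3. The direction of the ratio is not stated, and CO2 over air was taken as likely from the order of the channels and the design text. No spot intensities were used here, so whether a probe was near background or saturated is unknown, and the precision is limited by the number of arrays.

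Of 15744 probes, 8301 had no value on any array, 2632 had a value on 1 array, 1433 on 2 arrays and 3378 on all 3. Why values are absent is not stated. Each probe ID appeared once. The IDs have the form of 41 plates of 384 wells, and 0 of them occurred in the RefSeq gene table given for the species, so the table pairs no probe with a gene here. The gene lists fixed before the data were examined could therefore not be tested. The rule for named probes, also fixed then, allowed at most 2 probe IDs per direction when no gene names were given, taken as those with the largest mean log2 ratio among probes past the threshold with the same sign on all 3 arrays. Groups of probes are described by size.

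Each array was centred on the median of all its probes. Probes with a value on all 3 arrays were fitted in R 4.3.3 with limma 3.58.1 (lmFit with an intercept only, then eBayes), which tests the mean log2 ratio against 0, two-sided. P-values were adjusted by Benjamini-Hochberg over 3378 probes, with a threshold of 0.05. SDs are those of the 3 centred values. The fit was tested on simulated data for 3378 probes with the spread estimated from these arrays, in which 200 probes were changed, 50 at each of 4 sizes. It recovered 26% of the changes of 0.3, 96% of those of 0.5, 100% of those of 1 and 100% of those of 2 on the log2 scale. Of its calls, 3.59% were false. The simulated values were independent and normal, drawn from the variance model that limma itself fits. Their spread was unrelated to the size of the change, and the arrays shared no dye or position offset. These shares hold for that model only and do not give the error rate of the calls on the real arrays.

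The alternatives fixed before the data were examined were the deposited values without centring, scaling or quantile normalization between arrays, robust or no moderation of the variance, array weights, probes measured on at least 2 arrays, minimum changes of 0.5 or 1 on the log2 scale, a threshold of 0.1, and leaving out each array. Centring within print positions and centring on the probes common to all arrays were added after seeing the data. The array's print layout is not given in the sources used here. Print positions were taken as the well row modulo 4 and the well column modulo 12, which gives 48 positions. This layout was chosen on the data: its Kruskal-Wallis statistic for the mean log2 ratio was 476.7, against 248.7 to 289.1 for the 3 other layouts of 48 positions tried. A finer one of 96 positions gave 539.9 and 4 coarser ones gave 228.0 to 260.7. Permutation tests on plate layout used Python 3.11.15 with NumPy 2.4.6 and SciPy 1.17.1 and shuffled values within plates.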

Results

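The series asked how gene expression in adult Drosophila melanogaster changed under elevated carbon dioxide (hypercapnia). Whole-fly RNA came from 5-day-old flies of Oregon R, a laboratory wild-type strain, with both sexes in equal numbers and at least 40 flies in all. One set of flies had been kept in 13% CO2 for 24 h and the other in air for 24 h. On each of 3 two-colour microarrays, Cy5-labelled cDNA of CO2-exposed flies was hybridised together with Cy3-labelled cDNA of flies in air. Each array thus gave 1 log2 ratio per probe, with air as the reference channel measured beside CO2 on the same spot. The deposited table held 15744 probes. Array 1 had a ratio for 6617 of them, array 2 for 4682 and array 3 for 4333, and 3378 probes had a ratio on all 3 arrays. These 3378 probes form the comparison. Ratios are given as CO2 over air. This direction is the likely one, because CO2 RNA is the first channel in the labels and the series describes changes in CO2 compared with air, but the table itself does not state it. If the ratios run the other way, every "higher" below becomes "lower" with the same size. Probes are identified by plate position only and are not paired with genes here, so no gene or pathway is named.

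In flies kept in CO2, 121 probes had a lower signal than in air and 115 had a higher one, together 6.99% of the probes tested (limma, Benjamini-Hochberg adjusted p under 0.05, n = 3 arrays). The lower probes included changes far larger than any among the higher probes. Of the called probes with a change of at least 1 on the log2 scale, 27 were lower and 7 were higher. A change of at least 2 was seen for 14 lower probes and for none of the higher probes, whose largest mean was 1.89. Between 0.5 and 1, 53 called probes were lower and 41 higher, and under 0.5 the numbers were 41 lower and 67 higher. The median change was -0.62 among the 121 lower probes and 0.46 among the 115 higher probes. The median SD across the 3 arrays was 0.29 for the lower and 0.17 for the higher probes, against 0.14 for all probes tested.

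The strongest reductions formed a small set apart from the rest. Of the 27, 5 probes had mean log2 ratios between -5.63 and -4.99, which correspond to signals 31.9-fold to 49.4-fold lower in CO2 than in air. Each of the 5 was lower on all 3 arrays, and their SDs ran from 0.38 to 0.79 (n = 3). The 5 came from 3 plates, and those ranked 1, 2 and 4 were all on plate 10. Whether they stand for separate transcripts is unknown, because probes are not paired with genes here. The lowest was probe DAC010B22, at -5.63 ± 0.74 (SD, n = 3), a signal 49.4-fold lower in CO2, with an adjusted p of 1.79e-10 in the limma fit. Its values on arrays 1, 2 and 3 were -4.91, -6.38 and -5.59. That p rests on a variance drawn toward the one shared by all probes (prior SD 0.16). With robust moderation the probe's limma adjusted p was 0.029. The next was probe DAC010D02, at -5.57 ± 0.38 (SD, n = 3), which was 47.4-fold lower with an adjusted p of 2.3e-12 in the limma fit. The sixth probe of the ranking was at -3.62 ± 0.99 (SD, n = 3), 12.3-fold lower, and the twelfth was at -2.29 ± 1.13 (SD, n = 3), 4.90-fold lower. On the twelfth, array 3 gave -0.99 while arrays 1 and 2 gave -2.92 and -2.96, and its SD was the highest of the 12.

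**Figure D1:**
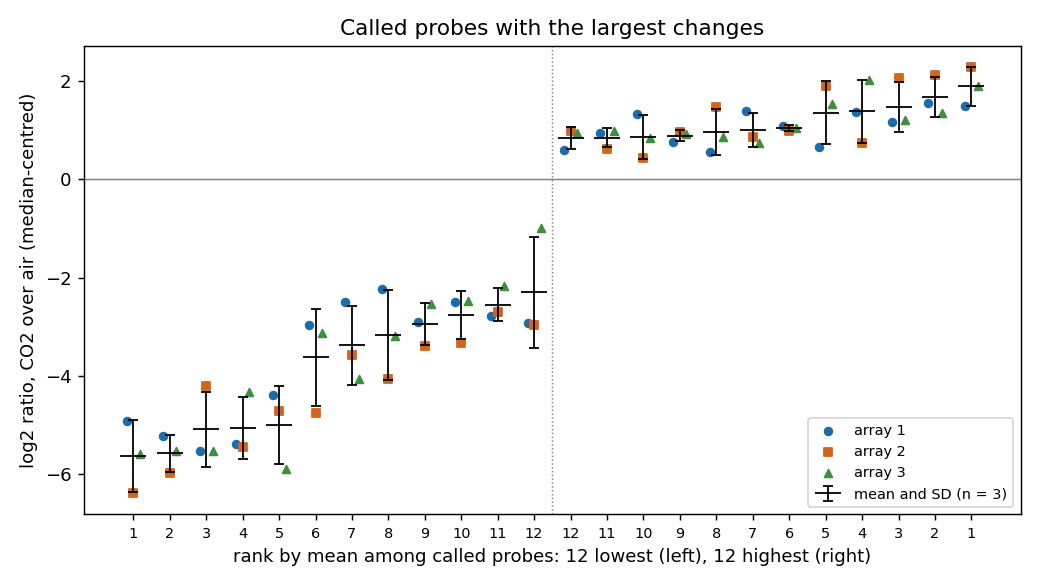
Log2 ratios of CO2 over air (vertical axis, each array centred on its median) for the 12 called probes with the lowest means (left) and the 12 with the highest means (right), ordered by mean on the horizontal axis; coloured symbols are the 3 arrays and black marks the mean and SD (n = 3). The 5 lowest probes lie between -5.63 and -4.99, whereas the highest probe reaches 1.89.

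Increases were smaller. Probe DAC016P04 had the largest, at 1.89 ± 0.39 (SD, n = 3), which is 3.71 times the signal in air, with an adjusted p of 2.47e-07 in the limma fit. Probe DAC006L13 followed at 1.68 ± 0.40 (SD, n = 3), 3.20 times the signal in air, with an adjusted p of 1.11e-06 in the limma fit. The next 3 probes rose by 1.48, 1.38 and 1.36, with SDs of 0.50, 0.64 and 0.64. The sixth probe rose by 1.05 with an SD of 0.05, a closer agreement between arrays than for any other of the 7 probes with a rise of at least 1. The twelfth probe stood at 0.84 ± 0.22 (SD, n = 3), 1.79 times the signal in air.

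**Figure D2:**
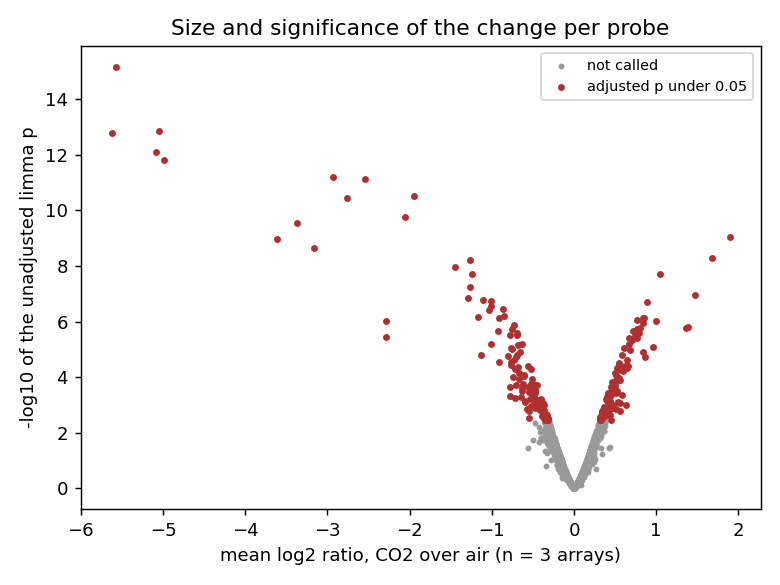
Mean log2 ratio of CO2 over air (horizontal axis, n = 3 arrays) against the unadjusted p of the limma fit as -log10 (vertical axis) for the 3378 probes measured on all arrays; red points have an adjusted p under 0.05. The red points number 121 on the left and 115 on the right, and only the left side extends beyond 2.

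The 3 arrays correlated positively in every pair. Across the 3378 probes, Pearson's r was 0.71 between arrays 1 and 2, 0.71 between arrays 1 and 3, and 0.76 between arrays 2 and 3. Spearman's rho for the same pairs was 0.40, 0.39 and 0.29. Without the 34 probes whose mean changed by at least 1, Pearson's r was 0.42, 0.41 and 0.45 and Spearman's rho was 0.39, 0.37 and 0.27, so the large changes raised Pearson's r far more than the rank correlation. These are correlations across probes of one set of arrays, and probes are not independent replicates. The sign of the ratio was the same on all 3 arrays for 1371 probes, or 40.6%, where independent arrays centred on 0 would give 25%. A dye effect or a print position offset shared by the arrays would also raise this share and the correlations. With each array centred within print positions, Spearman's rho over the 3378 probes was 0.35, 0.37 and 0.27 for the same pairs.

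The number of calls varied with how the ratios were processed and how the variance was estimated. With the ratios taken as deposited, without centring each array, limma called 0 higher and 2 lower probes (286 and 183 at an unadjusted p under 0.05). With each probe's own variance, not moderated across probes, it called 0 in either direction (164 higher and 172 lower at an unadjusted p under 0.05). Scaling the arrays to the same spread left 76 higher and 87 lower calls. Of the 34 called probes with a change of at least 1, only 2 stayed past the threshold without centring. Without moderation 0 did, and with robust moderation 26 did. All 34 did under each of the other alternative fits. Those include the fits that left out an array, which rest mostly on the variance shared across probes. The sign of the mean was kept for all 34 in every fit. This was bound to follow and is no separate support. Each of the 34 had the same sign on all 3 arrays, so leaving out 1 array could not turn it. The array medians, from -0.06 to 0.09, were far smaller than a change of 1. Moderation acts on the variance and leaves the means as they are. Probe DAC010B22 was at -5.62 without centring (limma adjusted p = 0.055) and at -5.63 without moderation (adjusted p = 0.45), so it was lost in both. With robust moderation its limma adjusted p was 0.029. Without centring, DAC016P04 was at 1.90 (limma adjusted p = 0.098), DAC006L13 at 1.69 (adjusted p = 0.10) and DAC010D02 at -5.56 (adjusted p = 0.020). Without moderation their adjusted p was 0.47, 0.47 and 0.45 with unchanged means. The ratios also varied with the position of the well in its plate, grouped into 48 print positions of a layout that was chosen on these data and not checked against the array's own. When each array was centred within print positions, 46 of the 108 calls under 0.5 remained, as did 81 of the 94 between 0.5 and 1 and 34 of the 34 of at least 1. In 100 random groupings of the same sizes, the medians kept were 78, 90 and 34. Each of these groupings kept all 34, so that outcome was bound to follow, and part of the other losses comes with any such centring.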

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

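Under the 12 alternative fits, the 4 named probes stayed past the threshold in 10 (DAC010B22, DAC016P04 and DAC006L13) or 11 (DAC010D02), and their highest adjusted p was 0.45 or 0.47, from limma without moderated variance. With the values as deposited, not centred, 0 probes were higher and 2 lower. The offsets between arrays then stayed in the values. The fitted prior degrees of freedom were 1.85 against 11.2, and the cause of this fall was not tested. Without moderation of the variance, 0 were higher and 0 lower. Scaled to the same median absolute value, 76 were higher and 87 lower, all of them among the main calls; the cause was not tested. A required change of at least 1 left 7 higher and 27 lower, and of at least 0.5 left 48 and 80, by construction. Robust eBayes gave 106 and 101, quantile normalization 111 and 118, array weights 114 and 122, probes on at least 2 arrays 114 and 143, and a threshold of 0.1 gave 158 and 157. Leaving out each array in turn gave 81 to 110 higher and 100 to 135 lower probes. These fits kept 68 to 84 of the 115 higher main calls and 82 to 105 of the 121 lower ones. The fit of probes on at least 2 arrays kept 88 and 103 of them. With 2 arrays left, a fit rests mostly on the prior variance. Its fitted degrees of freedom were 17.2 and 19.9 without arrays 1 and 3, and infinite without array 2. Added after seeing the data, centring within print positions gave 87 and 85, of which 79 and 82 were main calls, and, also added then, centring on the probes common to all arrays gave 116 and 121. The mean Pearson's r between arrays was 0.73, and 0.71 over all probes of each pair. Turning the sign of every array exchanges the counts. Testing probes on their own instead of averaging by gene changes nothing without gene names, and the gene list alternatives were not run for that reason. No paired analysis was possible because each array already holds the difference between its CO2 and air RNA and there is only 1 group of arrays.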

Other observations

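The tests of neighbouring wells and of plate or position offsets beside them, the print layout and the shuffles of print positions and the sign assignments were chosen after the results they concern had been seen; the checks of how many calls remain within print positions, of the position medians on odd and even plates, and of the dyes were set out before theirs.

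Probes left out of the comparison for lack of a value also included large reductions. Of the 1433 probes with a value on 2 arrays, 13 were at -1 or less on both and 0 were at 1 or more on both. Of the 3378 probes on 3 arrays, 15 were at -1 or less on each and 3 at 1 or more on each. Among the 2632 probes with a value on 1 array, 17 were at -1 or less and 13 at 1 or more. Most of those single values, 2248, came from array 1. Fewer values had to pass where fewer arrays held one, so the counts cannot be compared between these groups of probes. One whole plate, numbered 1 in the probe IDs, had no value on any array.

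The 27 probes at -1 or less came from 18 plates and 19 print positions, 5 of them from plate 10, which held 4 of the 7 lowest. If each plate was assembled from 4 interleaved plates of 96 wells, 3 pairs of the 27 were neighbours in that order, against a mean of 0.08 in 10000 shuffles within plates (permutation p = 0.0002, adjusted p = 0.002 over 10 distances), and 22 had no such neighbour. In the same order, 2 pairs lay 2 wells apart (permutation test, adjusted p = 0.01), 1 each lay 3 and 4 wells apart and 0 farther, up to 10 wells. The pairs 2 to 4 wells apart all lay among the same 4 probes of plate 10, from the same source plate. They repeat that run of wells and are not separate evidence. Neighbours by printed column, printed row or next dip of a print position gave 0 pairs. Shuffling gave means of only 0.05 to 0.07 pairs there, so these comparisons had no power. All 3 adjacent pairs came from plates 10 and 24, where the pattern had been noticed before it was tested, and the other plates had no power to test it (0 pairs, 0.02 by shuffling, permutation p = 1.0), so chance placement is neither excluded nor shown. An offset of a whole plate or print position is argued against, because the lowest median of the other probes at any such position or plate was -0.14, against a median of -2.06 for the 27.

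Over the 48 print positions of a layout chosen on these data, the medians of the mean log2 ratio ran from -0.14 to 0.10. The Kruskal-Wallis statistic was 476.7, and at least 248.7 for the 3 other layouts of 48 positions tried, against at most 81.6 in 2000 shuffles within plates of the chosen one (permutation p = 0.0005, the smallest they can give). Position medians from odd and even plates had a Spearman's rho of 0.90, so the offsets are consistent with a position effect common to all plates. Offsets from -0.14 to 0.10 are far smaller than a change of 1, so they do not account for the large changes. After centring within positions, 100% of the called probes of at least 1 remained. That outcome was bound to follow, since each of 100 random groupings also kept 34 of 34. Of the calls under 0.5, 42.6% remained, between the bounds set in advance. The latter are 46 of 108 calls, as few as the lowest of 100 random groupings of the same sizes, which left a median of 78, so what part of the loss is due to print position stays open.

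Whether the calls as a whole follow the exposure or the dye cannot be told apart, because the arrays with the dyes swapped number 0 and a gene-specific dye bias would repeat on every array. With 3 arrays there are 4 sign assignments, and 1 of them, the real one, reached 236 calls. The highest of the others gave 0 calls in limma (35, 54 and 69 probes at an unadjusted p under 0.05 when array 1, 2 or 3 was turned). So few assignments cannot give a share under 0.05.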
